A study of Mus musculus with 4 samples.

How the data were processed

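Messenger RNA was measured in 4 libraries of mouse liver tumors, 2 from carrier-treated mice and 2 from sorafenib-treated mice. Per the labels' protocols, the tumors were made by hydrodynamic injection of transposons carrying Myc and a mutant Nras into wild-type C57BL/6 mice, which delivers DNA to hepatocytes. Treatment lasted 3 weeks with a dose every second day. Poly(A) RNA was captured from 100 ng of total RNA, and stranded TruSeq libraries were read single-end with 75 cycles, per the labels. The submitters' processing notes name STAR 2.6.1c, Subread 1.6.3, edgeR 3.22.5 and the mouse build GRCm38. Which step each tool served, the strand setting of the counting and the treatment of reads with several matches are not given in the sources used here. Values of overlapping, antisense or near-identical genes are therefore uncertain.

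The authors deposited 1 table per library with 39179 genes and a value that the header calls reads. These deposited values are CPM, reads per 1000000 counted reads: each column summed to 1000000, and every value was a whole multiple of a single step. Dividing by that step recovered whole reads, within 0.01 of an integer, for 100% of the values above 0 in each library. The recovered totals were 5932939 and 5300806 reads for carrier replicates 1 and 2, and 4067427 and 5246530 reads for sorafenib replicates 1 and 2. In sorafenib replicate 1, the library with the fewest reads, 1 read equalled 0.246 CPM and a count of 0 allowed up to 0.738 CPM, the value of 3 reads. Wilson 95% intervals given with shares of reads cover counting error only.

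Groups and replicate numbers came from the sample labels. Nothing in the labels says that replicates came from separate mice. The p-values of single genes therefore measure only the spread between these libraries, which may be technical. Reads of replicates differed by more than sampling noise (chi-square per degree of freedom 9.09 for the carrier pair and 40.9 for the sorafenib pair), so each was counted as 1 library.

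The planned test, edgeR's quasi-likelihood test, needs counts, and the plan named limma on log2(value + 1) for normalized values. Because CPM were deposited, limma 3.58.1 (R 4.3.3) on log2(CPM + 1) was the main test, with empirical Bayes moderation and a mean-variance trend. Genes with at least 1 CPM in at least 2 libraries were tested, which left 13149 genes. The filter and the trend were chosen after the tables were seen. A log2 fold change is sorafenib minus carrier on the log2(CPM + 1) scale, which understates the change of genes with low values. Benjamini-Hochberg adjustment ran over all tested genes with a threshold of 0.05. edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as alternatives. DESeq2 left 8531 genes without an adjusted p.

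Before the data were examined, 37 gene lists with 857 symbols were fixed for lipid, bile acid and drug metabolism, signalling, growth, stress and the cell types a liver tumor can hold. 855 symbols matched. camera (limma) tested the 35 lists with at least 5 tested genes against all other genes, two-sided, with a preset inter-gene correlation of 0.01 and adjustment over the 35 lists. It ran on log2(CPM + 1) with the same variance trend, in place of the TMM-scaled log2 CPM with prior count 2 planned for counts, which was kept as an alternative. The same lists were tested by camera with an estimated correlation and by fry. With the preset correlation, camera judges a list against the spread of the statistics across genes. Its p-values therefore treat genes, not libraries, as the replicates, and are too small where genes of a list vary together by more than 0.01. With an estimated correlation, camera refers its statistic to the 2 residual degrees of freedom, so few lists can pass. Each list was also adjusted over the list alone with the p-values of its members.

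The rule for named genes was fixed at the same time. With no gene past the threshold, it took the 6 genes with the smallest p in each direction that have an assigned symbol, a mean log2 CPM of at least 2 and groups that do not overlap. It also took 17 genes named in advance (Myc, Nras, Scd1, Scd2, Fasn, Srebf1, Abca1, Abcg1, Nr1h3, Nr1h2, Dusp6, Spry4, Etv4, Kdr, Vegfa, Alb and Afp), the 2 members of each list with the smallest p in each direction, and other list members where their list is discussed. Gene positions came from GENCODE M21 on GRCm38, in which 37607 of the 39179 identifiers were found. For a symbol carried by more than 1 identifier (72 symbols), the identifier with the highest mean CPM was used.

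The scripts were tested on simulated reads for the 13149 genes of this comparison. With the spread seen between the carrier libraries, 37 of 50 genes changed 2-fold and 49 of 50 changed 4-fold were called, and 10 of 12638 unchanged genes were called. With the spread seen within both groups, 3 of 50 changed 2-fold, 35 of 50 changed 4-fold, 47 of 50 changed 8-fold and 49 of 49 changed 16-fold were called, with 23 of 12556 unchanged genes. Those 23 were 14.6% of the 157 calls, above the nominal 5%, against 10 of 196 (5.1%) with the carrier spread. camera called 1 of 1 simulated shifted lists and 0 of 36 unshifted ones. The simulated genes varied independently, each with the same spread in both groups. In the data the sorafenib pair differed more than the carrier pair (chi-square per degree of freedom 40.9 against 9.09), so the shares called need not hold for the real genes. Car3, with a log2 fold change of 2.47, was not called by limma. Nor does the simulation test camera on lists whose genes vary together. In the data the estimated correlation between genes of a list reached 0.973 (ribosomal protein genes). Alternatives covered scaling factors, pseudocounts, filters, the variance trend, other tools and thresholds, a replicate block, removal of the 20 most abundant genes and leaving out each library in turn.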

Results

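Gene expression was compared between liver tumors of mice given sorafenib and liver tumors of mice given carrier. Sorafenib is an oral inhibitor of several kinases, among them RAF kinases and the receptors of VEGF and PDGF, and the tumors were driven by Myc together with a constantly active Nras, which signals through RAF to ERK. Each group held 2 libraries. Depth was 5932939 and 5300806 reads in the carrier libraries and 4067427 and 5246530 reads in the sorafenib libraries, and 12005 to 13270 genes reached 1 CPM per library.

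Ces3b, a carboxylesterase, was at 261 ± 24.8 CPM in sorafenib against 45.8 ± 2.65 CPM in carrier tumors (SD, n = 2 each), a log2 fold change of 2.48 (SE 0.207). Oat, which breaks down ornithine, was at 884 ± 60.4 against 182 ± 26.7 CPM, and Hamp, the iron hormone hepcidin, at 1310 ± 386 against 139 ± 42.3 CPM. In the other direction, Gsn, the actin-severing protein gelsolin, was at 15.6 ± 1.6 against 56.5 ± 2.6 CPM, and Lgals3, galectin-3, at 3.82 ± 1.90 against 25 ± 6.57 CPM. No single gene passed the threshold: limma called 0 of 13149 genes, with a smallest adjusted p of 0.136. On CPM without scaling factors, 2529 genes had an unadjusted limma p below 0.05, 836 higher and 1693 lower in sorafenib tumors.

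The 6 genes with the smallest p in the upward direction, none past the threshold, were Ces3b (ENSMUSG00000062181, chromosome 8, 105083753 to 105093929 on GRCm38), Car3 (ENSMUSG00000027559, chromosome 3, 14863512 to 14872523), Oat (ENSMUSG00000030934, chromosome 7, 132557478 to 132576398), Hamp (ENSMUSG00000050440, chromosome 7, 30942368 to 30944032), Bhmt (ENSMUSG00000074768, chromosome 13, 93616675 to 93637961) and Upp2 (ENSMUSG00000026839, chromosome 2, 58567298 to 58792971). Car3, a carbonic anhydrase, had a log2 fold change of 2.47 (SE 0.213), Bhmt, which remethylates homocysteine, 1.83 (SE 0.196), and Upp2, a uridine phosphorylase, 1.79 (SE 0.207). Hamp has a near-identical neighbor, Hamp2, so its value is uncertain. The 6 in the downward direction were Gsn (ENSMUSG00000026879, chromosome 2, 35256380 to 35307892), Bhlha15 (ENSMUSG00000052271, chromosome 5, 144190286 to 144194441), Emilin1 (ENSMUSG00000029163, chromosome 5, 30913402 to 30921277), Nnt (ENSMUSG00000025453, chromosome 13, 119335448 to 119408997), Aldh1l2 (ENSMUSG00000020256, chromosome 10, 83487450 to 83534140) and Lgals3 (ENSMUSG00000050335, chromosome 14, 47367751 to 47386160). Bhlha15, a transcription factor of secretory cells, had a log2 fold change of -3.58 (SE 0.547), Aldh1l2, a mitochondrial folate enzyme, -2.87 (SE 0.477), Emilin1, a matrix glycoprotein, -1.58 (SE 0.247) and Nnt, the mitochondrial transhydrogenase, -1.27 (SE 0.203). All 12 are annotated as protein-coding, and their limma adjusted p ran from 0.136 to 0.24.

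The same absence of calls came from edgeR's quasi-likelihood test and limma-voom (0 genes each), while DESeq2 called 514 genes (461 higher, 53 lower) and the edgeR likelihood ratio test 657 (481 higher, 176 lower). Without sorafenib replicate 1, limma called 5149 genes, and without sorafenib replicate 2 it called 398, of which 373 were in both sets; the lone sorafenib library is then assumed to vary like the carrier pair.

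The 2 sorafenib libraries differed from each other more than the 2 carrier libraries did. On log2(CPM + 1), the Pearson correlation across genes, which are not independent replicates, was 0.978 between the carrier libraries and 0.937 between the sorafenib libraries. Sorafenib replicate 1 correlated at 0.961 with both carrier libraries, and sorafenib replicate 2 at 0.878 and 0.889. The first principal component, with 79.8% of the variance, set sorafenib replicate 2 apart. Both sorafenib libraries lay above both carrier libraries for 2299 genes (17.5%) and below both for 5430 (41.3%), where chance gives 16.7% per direction. These counts are on CPM without scaling factors, and genes that move together are not independent. The TMM factor was 0.837 in sorafenib replicate 2 against 1.104 and 1.065 in the carrier libraries. DESeq2 and the edgeR likelihood ratio test called mostly higher genes. Both scale the libraries, but whether scaling made that excess was not tested. The median log2 fold change of all tested genes was -0.259 on CPM. It was -0.0545, -0.0293 and -0.0116 with TMM, RLE and upper-quartile factors. On CPM it was -0.103 for sorafenib replicate 1 alone and -0.396 for sorafenib replicate 2 alone, each against both carrier libraries. A list median is to be read against the value for the same libraries and scaling.

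Both driver genes had lower values in the sorafenib tumors. Myc (ENSMUSG00000022346, chromosome 15, 61985391 to 61990374) was at 70.6 and 78.1 CPM in the carrier libraries and at 28.8 and 15.8 CPM in sorafenib replicates 1 and 2, a log2 fold change of -1.75 (SE 0.327, limma adjusted p = 0.24). Nras (ENSMUSG00000027852, chromosome 3, 103058285 to 103067914) was at 88.3 and 83.4 CPM against 47.0 and 22.1 CPM, a log2 fold change of -1.38 (SE 0.369, limma adjusted p = 0.24). These gene values do not separate transcripts of the injected transposons from those of the mouse's own genes. Nor do they separate lower expression within tumors from less tumor tissue in the sorafenib samples, a candidate explanation taken up below.

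Fetal liver genes that the carrier tumors expressed strongly were nearly absent from sorafenib replicate 2. H19, a fetal noncoding RNA, was at 19533 and 19388 CPM in the carrier libraries, 7796 CPM in sorafenib replicate 1 and 39.8 CPM in sorafenib replicate 2. Igf2, the fetal growth factor next to it, was at 12726, 10347, 5524 and 32.6 CPM, Afp, alpha-fetoprotein, at 5276, 2790, 1608 and 9.53 CPM, and Gpc3, a cell-surface proteoglycan of liver cancer, at 578, 510, 261 and 2.10 CPM in the same order. H19, Igf2 and Afp together took 3.75% (3.74 to 3.77, Wilson 95% interval), 3.25% (3.24 to 3.27), 1.49% (1.48 to 1.5) and 0.0082% (0.0075 to 0.0090) of the reads. The list of oncofetal and progenitor markers fell (limma camera, adjusted p = 0.00986; adjusted p = 0.586 with an estimated correlation), with 14 of 17 tested members lower and a median of -2.25 (-0.74 without sorafenib replicate 2). Prom1, a progenitor surface marker, was at 12.4 ± 11.6 against 52.1 ± 1.25 CPM and Igf2bp3, an RNA-binding protein of fetal tissue, at 0.246 ± 0.348 against 4.82 ± 0.384 CPM, and of the list's members only Igf2bp3 (1 gene) passed when adjusted over the list alone. No member of any list passed when adjusted over all 13149 genes.

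**Figure D1:**
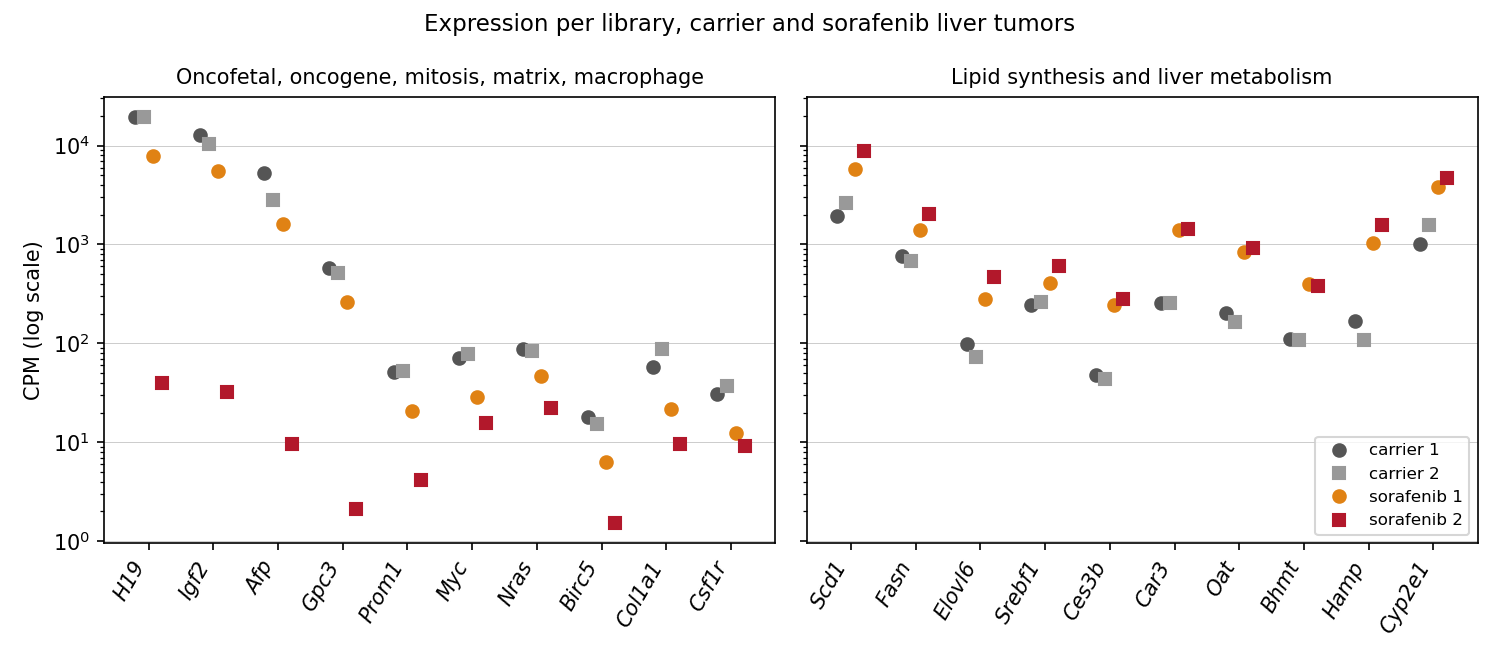
CPM of 20 genes in each of the 4 libraries on a log axis; each point is 1 library. In the left panel sorafenib replicate 2 is lowest for every gene, with H19 at 39.8 CPM against 19533 and 19388 CPM in the carrier libraries, and in the right panel both sorafenib libraries lie above both carrier libraries.

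Growth and proliferation genes fell as lists, and in every one the median was lower in sorafenib replicate 2 than in sorafenib replicate 1. All 28 nucleolar and MYC-regulated genes were lower in both sorafenib libraries than in both carrier libraries (limma camera, adjusted p = 4.11e-08; adjusted p = 0.586 with an estimated correlation), with medians of -0.55 and -1.57 in sorafenib replicates 1 and 2. Srm, which makes spermidine, was at 40.0 ± 19.6 against 117 ± 35.0 CPM and Cdk4, a G1 kinase, at 50.7 ± 21.8 against 120 ± 12 CPM. All 30 ribosomal protein genes were likewise lower (limma camera, adjusted p = 4.11e-08; adjusted p = 0.586 with an estimated correlation), with medians of -0.54 and -1.71, Rpl18 at 121 ± 40.7 against 257 ± 5.72 CPM and Rpl5 at 81.1 ± 40.8 against 207 ± 5.49 CPM. All 30 genes of G2/M and mitosis had negative fold changes (limma camera, adjusted p = 1.81e-06; adjusted p = 0.586 with an estimated correlation), with medians of -0.60 and -2.58 in sorafenib replicates 1 and 2. Birc5, survivin, was at 3.96 ± 3.44 against 16.7 ± 2.07 CPM and Cenpf, a kinetochore protein, at 2.69 ± 2.46 against 10.5 ± 0.586 CPM.

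The G1/S and DNA replication list also fell, with 24 of 28 members lower and medians of -0.39 and -1.26 in sorafenib replicates 1 and 2 (limma camera, adjusted p = 0.0152; adjusted p = 0.61 with an estimated correlation). Its adjusted p was 0.0661 without carrier replicate 1. Mcm4, part of the replicative helicase, was at 3.00 ± 2.36 against 11.5 ± 1.35 CPM, while Mcm10 was at 48.2 ± 1.65 against 29.7 ± 3.81 CPM. In none of these 4 growth lists did a member pass when adjusted over the list alone.

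Transcripts that ERK signalling induces fell, with 17 of 19 tested members lower and a median of -1.11 (limma camera, adjusted p = 0.00142; adjusted p = 0.586 with an estimated correlation). The medians were -0.62 in sorafenib replicate 1 and -1.64 in sorafenib replicate 2, and 0 members passed when adjusted over the list alone. Ccnd1, cyclin D1, was at 16.8 ± 0.270 against 37.3 ± 3.20 CPM and Ier3, an immediate early gene, at 4.97 ± 5.14 against 28.2 ± 3.80 CPM. The ERK feedback phosphatase Dusp6 was at 78.2 ± 4.53 against 79.3 ± 40.9 CPM (limma adjusted p = 0.911), the feedback inhibitor Spry4 at 10.2 ± 3.95 against 14.6 ± 3.68 CPM, and the ETS factor Etv4 at 1.79 ± 1.99 against 4.73 ± 1.89 CPM. Among genes of the kinases that sorafenib inhibits, 11 of 13 were lower with a median of -0.46, or -0.23 with upper-quartile factors. The list did not pass (limma camera, adjusted p = 0.168). Kdr, VEGF receptor 2, was at 13.9 ± 6.74 against 30.4 ± 7.96 CPM, and 1 member, Csf1r, at 10.8 ± 2.40 against 33.9 ± 4.08 CPM, passed when adjusted over the list alone. Kdr and Csf1r stand in the endothelial and macrophage lists too, whose medians were -1.11 and -1.29. Vegfa, the ligand of that receptor, was at 344 ± 85.2 against 157 ± 15.7 CPM, a log2 fold change of 1.11 (SE 0.25, limma adjusted p = 0.24).

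Fatty acid synthesis and desaturation genes rose as a list, with 18 of 24 members higher, medians of 0.67 and 1.07 in sorafenib replicates 1 and 2, and 14 of 24 above both carrier libraries in both (limma camera, adjusted p = 4.11e-08; adjusted p = 0.285 with an estimated correlation). When adjusted over the list alone, 14 members passed, 13 higher and 1 lower. Scd1, the main liver desaturase, was at 7348 ± 2154 against 2274 ± 473 CPM, Fasn, fatty acid synthase, at 1734 ± 448 against 722 ± 67.1 CPM, Elovl6, a fatty acid elongase, at 376 ± 138 against 85.4 ± 18.9 CPM, and Srebf1, the transcription factor of this pathway, at 507 ± 141 against 253 ± 11.7 CPM. Scd2, another desaturase, was at 443 and 403 CPM in the carrier libraries and at 293 and 7.05 CPM in sorafenib replicates 1 and 2. Fads2, a desaturase of polyunsaturated fatty acids, was at 139 ± 74.8 against 293 ± 46.3 CPM.

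Targets of the oxysterol receptor LXR rose as a list (limma camera, adjusted p = 0.00298; adjusted p = 0.511 with an estimated correlation), with 12 of 20 members higher and a median of 0.47. Its mean was 0.03, and the median was 0.11 and 0.28 in sorafenib replicates 1 and 2, 0.31 without carrier replicate 2 and 0.75 with upper-quartile factors. Its adjusted p was 0.0545 without sorafenib replicate 1. The 6 members that passed when adjusted over the list alone were all higher: Fasn, Scd1, Srebf1 and Mlxipl, which are lipogenic genes and stand in the fatty acid list too, and Abcg5 and Abcg8, which export sterols into bile. Abcg5 was at 223 ± 43.6 against 102 ± 4.07 CPM. The cholesterol efflux genes did not share that direction: Abca1 was at 244 ± 49.3 against 311 ± 30.4 CPM and Abcg1 at 4.28 ± 2.29 against 10.4 ± 1.08 CPM. The fold change of Abca1 was -0.36 on CPM (limma adjusted p = 0.403) and -0.08 with upper-quartile factors. That of Abcg1 was -1.17 (limma adjusted p = 0.258) and -0.94. The receptor genes were at 83.7 ± 14.1 against 95.1 ± 13.1 CPM for Nr1h3 (LXR alpha) and 45.7 ± 0.741 against 57.2 ± 10.2 CPM for Nr1h2 (LXR beta), with limma adjusted p of 0.663 and 0.469. The fold change of Nr1h3 was -0.18 on CPM and 0.05 with TMM factors.

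Genes of fatty acid oxidation and PPARA targets rose, with 25 of 30 members higher and medians of 0.31 and 0.94 in sorafenib replicates 1 and 2 (limma camera, adjusted p = 5.28e-09; adjusted p = 0.586 with an estimated correlation). Cyp4a10, a fatty acid hydroxylase, was at 520 ± 335 against 95.3 ± 24.0 CPM and Acaa1b, a peroxisomal thiolase, at 1081 ± 983 against 131 ± 35.6 CPM, with 0 members past when adjusted over the list alone. The triglyceride list passed in the same direction, with 18 of 27 members higher and a median of 0.27. Its adjusted p was 0.00684 by limma camera, or 0.586 with an estimated correlation. The list had a median of 0.15 without carrier replicate 2 and 0.55 with upper-quartile factors, where its adjusted p was 0.0325 (limma camera). It did not pass without carrier replicate 2 (adjusted p = 0.0758) or without sorafenib replicate 2 (adjusted p = 0.0943), and 0 members passed when adjusted over the list alone. Mgll, a monoacylglycerol lipase, was at 192 ± 91.2 against 65.8 ± 19.2 CPM, while the lipid droplet genes Hilpda and Cidec were at 6.11 ± 3.52 against 21.2 ± 3.58 CPM and 3.37 ± 0.451 against 9.88 ± 0.0952 CPM. Cholesterol synthesis genes did not pass (limma camera, adjusted p = 0.19), with 13 of 25 higher, a median of 0.12 and a mean of -0.07. With TMM and upper-quartile factors the median was 0.35 and 0.40. On CPM it was -0.02 and 0.07 without carrier replicates 1 and 2, and 0.002 and -0.01 without sorafenib replicates 1 and 2.

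The list of gluconeogenesis, the urea cycle and amino acid breakdown rose, with 27 of 31 members higher, 26 of them in both sorafenib libraries above both carrier libraries, with medians of 0.95 and 1.23 in sorafenib replicates 1 and 2 (limma camera, adjusted p = 2.41e-21; adjusted p = 0.285 with an estimated correlation). When adjusted over the list alone, 27 members passed, 26 higher and 1 lower; the lower one was Pck2, the mitochondrial form of PEP carboxykinase, at 18.9 and 4.77 CPM in the sorafenib libraries against 44.7 and 39.4 CPM. Drug and xenobiotic metabolism rose with 23 of 31 members higher and a median of 0.95 (limma camera, adjusted p = 9.13e-11; adjusted p = 0.586 with an estimated correlation), and 17 members, 15 higher and 2 lower, passed when adjusted over the list alone. Ces1f, a carboxylesterase, was at 292 ± 108 against 62.1 ± 10.1 CPM and Cyp1a2 at 571 ± 225 against 162 ± 16 CPM, whereas the drug efflux pump Abcb1a was at 9.08 ± 0.715 against 26.1 ± 8.12 CPM.

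Bile acid genes rose with 17 of 20 members higher and medians of 0.90 and 0.91 in sorafenib replicates 1 and 2 (limma camera, adjusted p = 9.13e-11; adjusted p = 0.285 with an estimated correlation). It was the only list of the 35 past the threshold by fry, which asks whether a list moves one way on balance (limma fry, adjusted p = 0.0424). Cyp27a1, a sterol hydroxylase, was at 503 ± 80.5 against 184 ± 34.9 CPM and Baat, which conjugates bile acids, at 225 ± 3.42 against 103 ± 12.2 CPM, and 11 members, 10 higher and 1 lower, passed when adjusted over the list alone. General hepatocyte markers also passed, placed above the rest by camera, with 14 of 27 higher and a median of 0.09 (limma camera, adjusted p = 0.0164; adjusted p = 0.586 with an estimated correlation), and 0 passed when adjusted over the list alone. The median was 0.08 in sorafenib replicate 1 and -0.02 in sorafenib replicate 2, -0.14 and 0.01 without carrier replicates 1 and 2, and 0.32 to 0.37 with other scaling factors. That call was lost with TMM, RLE or upper-quartile factors (adjusted p = 0.0512, 0.0614 and 0.066), without carrier replicate 1 (adjusted p = 0.0947) and without sorafenib replicate 1 (adjusted p = 0.0858). Cyp2e1 was at 4284 ± 646 against 1288 ± 404 CPM, and Alb, serum albumin, at 75652 ± 5593 against 99553 ± 11259 CPM (limma adjusted p = 0.831).

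Both lists of respiratory genes rose. Of 32 nuclear genes of oxidative phosphorylation, 26 were higher with medians of 0.11 and 0.32 in sorafenib replicates 1 and 2, and 0.50 over both with upper-quartile factors (limma camera, adjusted p = 1.37e-06; adjusted p = 0.586 with an estimated correlation), Ndufb10 at 164 ± 21.7 against 97.0 ± 10.8 CPM and Cox5b at 137 ± 1.04 against 85.9 ± 6.08 CPM. All 7 tested mitochondrially encoded genes were higher in both sorafenib libraries than in both carrier libraries, with medians of 0.53 and 0.97 (limma camera, adjusted p = 0.000106; adjusted p = 0.586 with an estimated correlation). No member of either list passed when adjusted over the list alone. Mitochondrial transcripts took 3.59% and 3.67% of the reads in the carrier libraries, 5.34% in sorafenib replicate 1 and 7.65% in sorafenib replicate 2. mt-Nd2 was at 10639 ± 5174 against 4308 ± 387 CPM. The mitochondrial genes mt-Co2, mt-Co3, mt-Atp6, mt-Atp8, mt-Nd3 and mt-Nd4l were listed at 0 or at 1 read in every library.

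**Figure D2:**
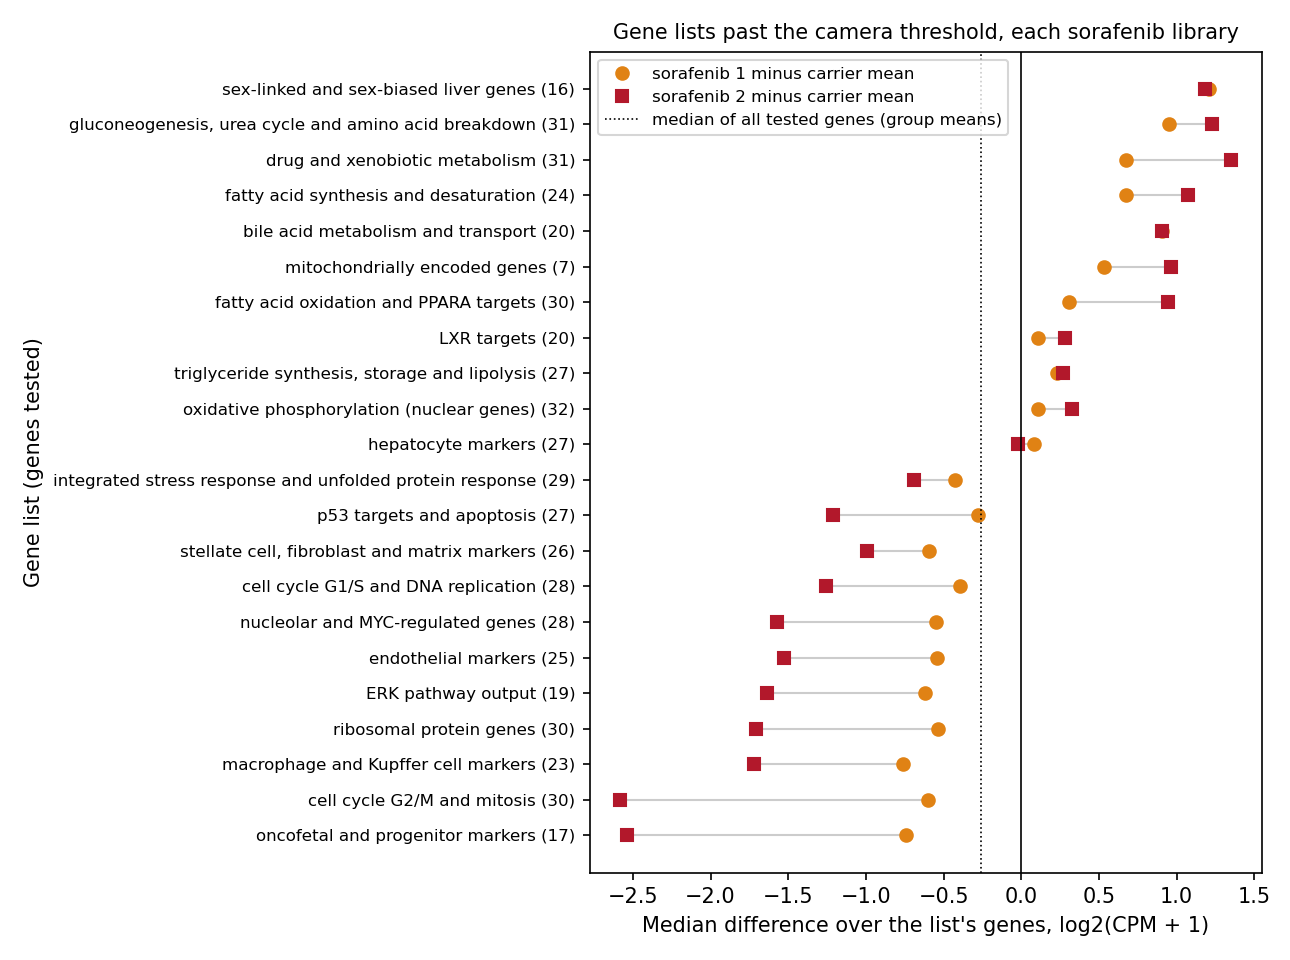
Median difference from the carrier mean on log2(CPM + 1) for each sorafenib library, over the tested genes of the 22 lists past the camera threshold. The dotted line marks the median log2 fold change of all tested genes over both sorafenib libraries, -0.259. For sorafenib replicates 1 and 2 alone that median was -0.103 and -0.396. Oncofetal and mitosis lists reach -2.54 and -2.58 in sorafenib replicate 2, against -0.74 and -0.60 in sorafenib replicate 1.

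The list of the integrated stress response and unfolded protein response fell, with 25 of 29 members lower and a median of -0.56, or -0.30 with upper-quartile factors (limma camera, adjusted p = 0.00167; adjusted p = 0.586 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, was at 567 ± 150 against 1245 ± 89.9 CPM and Sdf2l1 at 25.9 ± 5.09 against 68.2 ± 11.8 CPM. The list of p53 targets and apoptosis fell with 24 of 27 members lower and medians of -0.28 and -1.21 in sorafenib replicates 1 and 2 (limma camera, adjusted p = 0.0164; adjusted p = 0.637 with an estimated correlation), but not without sorafenib replicate 2 (adjusted p = 0.0943). Bcl2l1, which opposes apoptosis, was at 51.9 ± 16.6 against 93.2 ± 4.54 CPM. No member of either list passed when adjusted over the list alone.

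Lists of hypoxia response, glycolysis, NRF2 and oxidative stress, ferroptosis, interferon response and MHC antigen presentation did not pass (limma camera, adjusted p = 0.354, 0.939, 0.0907, 0.333, 0.0655 and 0.391), and 0 of their members passed when adjusted over the list alone. The medians of hypoxia (-0.09), glycolysis (-0.36) and ferroptosis genes (-0.02) were negative although camera, which compares with all other genes, placed these lists above the rest. The medians of hypoxia, ferroptosis and MHC genes changed sign with other scaling factors. Those of interferon and glycolysis genes stayed negative, at -0.14 and -0.12 with upper-quartile factors. Leaving out 1 library turned the sign for hypoxia (0.06 without sorafenib replicate 1) and ferroptosis genes (0.12 without carrier replicate 1, 0.07 without sorafenib replicate 2), and the glycolysis median was -0.61 and -0.10 without sorafenib replicates 1 and 2. Interferon genes had a median of -0.40, and without sorafenib replicate 1 the list passed towards lower values (adjusted p = 0.0027, median -0.84). Without sorafenib replicate 2 its median was 0.04 and camera placed it above the rest (adjusted p = 0.79). Acute phase and cytokine genes did not pass either (limma camera, adjusted p = 0.449). camera placed them above the rest with a median of -0.44, or -0.24 with upper-quartile factors and -0.07 without sorafenib replicate 2. When adjusted over the list alone, 2 members passed, Hamp and the acute phase gene Orm3.

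The lists of endothelial, macrophage and stellate cell markers fell. All 25 endothelial markers had negative fold changes with a median of -1.11 (limma camera, adjusted p = 6.93e-05; adjusted p = 0.586 with an estimated correlation), and Lyve1 was at 3.06 ± 0.547 against 11.9 ± 1.07 CPM. Macrophage and Kupffer cell markers fell with 22 of 23 lower and a median of -1.29 (limma camera, adjusted p = 1.92e-05; adjusted p = 0.586 with an estimated correlation), and 10 passed when adjusted over the list alone. Adgre1, the F4/80 antigen, was at 1.21 ± 0.369 against 6.73 ± 1.42 CPM. Stellate cell, fibroblast and matrix markers fell with 22 of 26 lower and a median of -0.88 (limma camera, adjusted p = 0.00367; adjusted p = 0.586 with an estimated correlation), and 8 passed when adjusted over the list alone, 7 lower and 1 higher. Col1a1, a chain of collagen I, was at 15.6 ± 8.56 against 72.8 ± 21.9 CPM. For these 3 lists the medians were -0.54, -0.76 and -0.59 in sorafenib replicate 1 and -1.53, -1.72 and -0.996 in sorafenib replicate 2, and 0 endothelial markers passed when adjusted over the list alone.

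Cholangiocyte, erythroid, T and NK cell, and B, plasma and dendritic cell markers did not pass (limma camera, adjusted p = 0.248, 0.073, 0.553 and 0.19). Their medians were -0.67, -0.82, -0.14 and -0.01 (mean of the last 0.04), and camera placed the T and NK list and the B, plasma and dendritic list above the rest; both medians were positive with other scaling factors. With 1 library left out, the T and NK median ranged from -0.26 to -0.02 and the B, plasma and dendritic median from -0.26 to 0.20. The cholangiocyte median was -0.44 without sorafenib replicate 1, and the erythroid median -1.42 and -0.42 without sorafenib replicates 1 and 2. Without carrier replicate 1 the cholangiocyte and erythroid lists passed towards lower values (adjusted p = 0.0164 and 0.0174), as did the cholangiocyte list without sorafenib replicate 2 (adjusted p = 0.0209) and the erythroid list without sorafenib replicate 1 (adjusted p = 0.0155) or with TMM factors (adjusted p = 0.0246). When adjusted over the list alone, 1 erythroid gene passed, Slc4a1, the red cell anion exchanger, at 0.246 ± 0.348 against 4.36 ± 0.0307 CPM, and none of the other 3 lists had one. Only 3 neutrophil markers and 3 adipose, pancreas and muscle markers reached the filter, too few to test. Their medians were -1.03 and -0.76 (means -1.05 and 0.19), -0.08 and 0.35 without sorafenib replicate 2, and -1.76 and -1.30 without sorafenib replicate 1, with 1 neutrophil marker (lower) and 2 of the other list (1 higher, 1 lower) past the threshold when adjusted over the list alone.

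Sex-biased liver genes rose as a list, with 13 of 16 tested members higher and medians of 1.21 and 1.18 in sorafenib replicates 1 and 2 (limma camera, adjusted p = 3.78e-07; adjusted p = 0.285 with an estimated correlation). Without carrier replicate 1 the median was 0.65. When adjusted over the list alone, 6 members passed, all higher. Genes known as female-biased and as male-biased were both among the higher ones: Cux2, a female-biased transcription factor, was at 110 ± 80.1 against 12.1 ± 10.7 CPM, and Cyp7b1, a male-biased hydroxylase, at 28.2 ± 1.55 against 9.18 ± 0.353 CPM. Xist, the RNA of the inactive X chromosome, was at 1335 and 1343 CPM in the carrier libraries and at 1438 and 810 CPM in sorafenib replicates 1 and 2. The 4 Y-linked genes of the list had 0 reads in all 4 libraries.

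All 22 lists past the threshold kept their camera direction without sorafenib replicate 2, but the triglyceride and p53 calls were lost. With an estimated correlation 0 passed, and the smallest adjusted p was 0.285 (limma camera). That correlation was 0.973 for ribosomal protein genes, but -0.0242, -0.0476 and -0.0479 for the bile acid, LXR and sex-biased lists. These lie below the preset 0.01, and those calls were lost as well. With 2 residual degrees of freedom, a lost call does not by itself tell whether correlated genes made it.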

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

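TMM factors, pseudocounts 0.5 and 5 and a variance without a trend were chosen as alternatives after the data were seen. edgeR's quasi-likelihood test and TMM with prior count 2, planned as the main tests for counts, became alternatives once the values proved to be CPM; the others were planned as alternatives. The count of 0 genes stayed 0 with other scaling factors, filters, pseudocounts, an adjusted p of 0.10 and edgeR's quasi-likelihood test (2190 genes at an unadjusted p below 0.05), but was 514 with DESeq2 and 657 with the edgeR likelihood ratio test, and 0 to 5149 when 1 library was left out; the cause was not tested. The 22 list calls became 0 with an estimated correlation and 1 with fry. When 1 library was left out, which lists were called depended on the library. The LXR, triglyceride, G1/S, hepatocyte and p53 calls were each lost in at least 1 such fit. Cholangiocyte, erythroid and interferon lists were gained in others. Replicate numbers are shared by the labels alone: the difference between carrier replicates 1 and 2 correlated at 0.15 across genes with that between sorafenib replicates, and a replicate block gave 0 genes and 23 lists, the 22 called without it and the erythroid list. Lists that were not called changed direction with fry for cholesterol synthesis (adjusted p = 0.898), hypoxia (0.612), glycolysis (0.383), ferroptosis (0.766), acute phase (0.766) and T and NK cell genes (0.332). Glycolysis also did so with RLE (0.963), upper-quartile (0.968) and TMM factors (0.968), TMM with prior count 2 (0.964) or 0.5 (0.969) and the block (0.969). With 1 library left out, the adjusted p ranged over 0.151 to 0.767 for hypoxia, 0.675 to 0.883 for glycolysis, 0.0027 to 0.79 for interferon and 0.139 to 0.963 for acute phase genes, each with 1 change of direction. Nr1h3, at -0.18, was at 0.0463, 0.0749 and 0.0939 with TMM, RLE and upper-quartile factors, 0.061, 0.0609, 0.061 and 0.0608 with edgeR's quasi-likelihood, legacy, robust and likelihood ratio tests, 0.0686 with limma-voom and 0.0706 with DESeq2. Left-out libraries moved Cyp7a1 over -1.07 to 2.29, Dusp6 over -0.466 to 0.622 and Xist over -0.724 to 0.103 (log2). For the 80 named genes, 1370 of the alternative values kept direction and stayed uncalled, 210 kept direction and were called and 12 changed direction. Depth limits genes below 0.738 CPM, where sorafenib replicate 1 has under 3 reads.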

Other observations

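All tests in this part were chosen after the results they concern were seen. Gene families were formed from shared symbol roots with 8 to 100 tested genes. Of 205 families, 18 passed limma camera with a preset correlation, 11 towards higher and 7 towards lower values in sorafenib tumors, and none passed with an estimated correlation (smallest adjusted p = 0.994). The major urinary proteins (Mup), liver pheromone carriers, had 19 of 20 genes higher with a median log2 fold change of 1.13 (limma camera, adjusted p = 5.98e-12; adjusted p = 0.994 with an estimated correlation), although these genes are near-identical copies whose reads are hard to tell apart. The Cyp2c family of drug and steroid hydroxylases had 12 of 13 genes higher with a median of 1.40 (limma camera, adjusted p = 9.82e-09; adjusted p = 0.994 with an estimated correlation), and the Acot family of acyl-CoA thioesterases 9 of 11 higher with medians of 0.46 and 1.17 in sorafenib replicates 1 and 2 (limma camera, adjusted p = 0.000252; adjusted p = 0.994 with an estimated correlation).

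Towards lower values, the nucleoporins (Nup) had 19 of 19 genes lower with medians of -0.35 and -1.16 in sorafenib replicates 1 and 2 (limma camera, adjusted p = 0.00499; adjusted p = 0.994 with an estimated correlation). The Eif root, named after translation initiation factors, had 45 of 51 genes lower with medians of -0.39 and -0.84. The Eef root, named after elongation factors, had 8 of 8 lower with medians of -0.57 and -1.50. Their adjusted p by limma camera was 0.000766 and 0.0259, or 0.994 with an estimated correlation for both. Genes were placed in both families by symbol alone, so not every member need be such a factor. Over both sorafenib libraries, the Eif median was -0.64 on CPM and -0.36 with upper-quartile factors, and none of the 6 medians changed sign with TMM, RLE or upper-quartile factors.

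Sorafenib replicate 2 held almost no transcripts of genes abundant in the carrier tumors, and sorafenib replicate 1 lay between: for 79 genes at 20 CPM or more in carrier tumors and at most 5% of that in sorafenib replicate 2, the median ratio of sorafenib replicate 1 to carrier was 0.524 (quartiles 0.407 and 0.672). A few genes taking most of the reads cannot account for it. The 20 most abundant genes took 27.3% and 28.5% of the reads in the carrier libraries and 24.2% in sorafenib replicate 2. This shifts all others up by 0.0724 (log2) in sorafenib replicate 2, against the direction of the loss. Those 79 genes were at a median of -4.53, a size set by their choice at 5% or less. A candidate explanation is less tumor and more non-tumor liver in the sorafenib samples: a mixture of the carrier mean and sorafenib replicate 2 at that ratio left sorafenib replicate 1 a residual SD of 0.281 over 6009 other genes, against 0.449 for the carrier mean unmixed and 0.273 that carrier noise alone would leave. The 238 genes at least 3 times higher in sorafenib replicate 2 lay at a median of -0.289 (log2) from the mixture. They were chosen by a high value in that library, which is an end of the mixture. This choice pulls the median below 0 by an amount that was not measured. A carrier share above 0.524, such as the best-fitting 0.61 given below, would also place the mixture lower for these genes. How much of the -0.289 is misfit therefore stays unknown. Single genes lay far from the mixture: Pdk4, a kinase of fasting metabolism and in that set, at -2.26, and Cyp7a1, outside that set, at 2.67. A graded response inside the tumors cannot be told apart from a mixture. Every sorafenib library holds drug effect and tissue share together, and sorafenib replicate 2 as the pure end is an assumption. Interpolation on the log scale left 0.279 over the 6009 genes (0.264 from carrier noise). Its weight of 0.67 was fitted over 6066 genes that include them, unlike the share of the mixture, so 0.279 and 0.281 are not like for like. With both weights fitted over the 6066 genes, the interpolation left 0.295 against 0.276 for the mixture, whose best carrier share was 0.61.

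Sex-biased liver genes were higher as a list in the sorafenib libraries, and A1bg, a female-biased liver gene chosen after its values were seen, was at 1.18, 0.755, 8.6 and 86.9 CPM in carrier replicates 1 and 2 and sorafenib replicates 1 and 2. Mice of different sex in the 2 groups are excluded, since the lowest Xist value was 810 CPM and the Y-linked genes had 0 reads in all 4 libraries. Other tissue share or a response to the drug stay open.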
